A study of Drosophila melanogaster with 4 samples.

How the data were processed

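Gene expression was measured on 4 one-colour Affymetrix arrays hybridised with biotin-labelled RNA, 2 from wild-type (yw) embryos and 2 from *how* germline-clone mutant embryos, both aged 3 to 5 h at 25 °C. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 intensity value per probe set and array, the signal that MAS5 gives, per the submitters' processing notes; its version and settings are not given in the sources used here. The values are on a linear scale: the mean signal without the highest and lowest 2% was 250.04 on each array, so the arrays had been scaled to a common mean, and no further normalization was applied for the main results. The number of arrays limits the precision: with 2 against 2 the smallest two-sided p of an exact permutation test is 0.333, so p-values rest on a model that shares the spread across probe sets. The labels speak of independent samples; each array pools 5 RNA preparations, so the spread between embryos or single preparations was not measured. Detection calls were not used here.

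Signals under the 5th percentile of all gene probe set signals (3.38) were set to it, and log2 was taken. The 44 control probe sets were left out of tests. Probe sets whose mean log2 signal lay under the 40th percentile (a signal of 39.5) were left out, which kept 8380 of 13966. Each was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, prior degrees of freedom 5.80, residual degrees of freedom 2), and called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are mutant minus wild type, with limma's SE. As a count free of the model, probe sets were also counted whose mutant arrays all lay at least 2-fold above or below both wild-type arrays.

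Probe sets were named through the platform's annotation, with symbols updated by Entrez ID to the RefSeq gene table of Release 6 plus ISO1 MT. Of the gene probe sets, 12443 had 1 gene symbol, 327 had several and 1196 had none; 12394 of the first were matched, for 10845 genes. Probe sets with several symbols were not named, and *how*, *stg*, *wg*, *Mef2* and *Mhc* are among genes with no named probe set here. Chromosome arms and distances to *how* come from the same assembly. A gene with several probe sets is represented by the brightest; of 9 changed genes with several, 2 changed in every probe set and 1 (*siz*, -0.81 and 0.45) had probe sets of opposite sign.

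The 30 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the HOW-linked genes, the 12 largest rises and the 12 largest falls among genes that passed with arrays of the groups not overlapping, and from each other list up to 4 passing members by size or, where none passed, the 2 with the smallest p. A few others (*twi*, *sna*, *y*, *Cyp4e2*) were added after their values were seen. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01; the estimated correlation and fry were alternatives. The share of changed genes on 3R was tested with Fisher's exact test against all tested genes with a known arm.

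The steps were tested on simulated data with 200 of 8380 probe sets changed: limma recovered 1.94% of 1.5-fold, 26.9% of 2-fold and 74.8% of 4-fold changes, 5.5% of the calls were unchanged probe sets, and 10 runs with no change gave 0 calls. The values were drawn independently for each probe set from normal distributions with the spread that limma had fitted, and without an effect of replicate number. These rates therefore hold under limma's own model and do not test whether the real arrays follow it. Alternatives were the replicate number as a block, quantile normalization, median centring, no filter, a filter at the 60th percentile, 50 added to each signal in place of the floor, no trend, a robust fit, other thresholds and leaving out each array in turn.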

Results

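Transcript levels were measured in whole *Drosophila melanogaster* embryos aged 3 to 5 h after egg laying at 25 °C. Wild-type embryos of the yw stock were compared with embryos from *how* germline-clone mothers, from which homozygous mutants had been picked under a fluorescence microscope. *how* (*held out wings*) encodes a STAR-family RNA-binding protein that acts in mesoderm, muscle and glia. Each group had 2 one-colour Affymetrix arrays, and per the labels the RNA for an array was pooled from 5 preparations of about 100 embryos. The arrays carried 14010 probe sets, 44 of them controls. The median signal of the gene probe sets was 76.1 and 79.8 on the wild-type arrays and 82.1 and 75.5 on the mutant arrays. No probe set was named *how* in the annotation used, so the level of *how* itself was not analysed here and the genotype was not checked from the signals.

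The first question was which transcripts differed between embryos lacking HOW and wild-type embryos. Among genes that passed the filter on dim probe sets and the test, the 12 largest falls included cuticle genes, 1 muscle gene and several genes of other or unstated function. *Osi6*, an Osiris gene active in cuticle-forming epithelium, went from a signal of 875 ± 94.7 in wild type to 13.6 ± 9.75 in the mutant (SD, n = 2), a log2 change of -6.22 ± 0.49 (SE). The Tweedle cuticle gene *TwdlN* changed by -5.55, the cuticle protein genes *Ccp84Ag* and *Cpr65Ea* by -4.40 and -4.25, and the myosin light chain gene *Mlc1* by -4.48. The 12 largest rises included the heat shock cognate gene *Hsc70-2*, from 16.9 ± 2.49 to 448 ± 16.1 (SD, n = 2), a log2 change of 4.74 ± 0.30 (SE).

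The other falls among the 12 largest were in *CG13794* (-5.25), *CG13361* (-4.88), *CG9083* (-4.28), the Osiris gene *Osi14* (-4.26), the metallothionein gene *MtnA* (-4.18), *IM33* (-3.95) and *CG4408* (-3.71). The other rises among the 12 largest were in *CG42324* (4.77), *CG7650* (3.86), the peptidoglycan recognition gene *PGRP-SB1* (3.81), *miple1* (3.78), *CG14502* (3.58), the ornithine aminotransferase gene *Oat* (3.07), *RpS10a* (3.03), *CG5973* (3.03), the glutathione transferase gene *GstE3* (2.76), *CG2065* (2.71) and *axed* (2.53). In limma's moderated test with Benjamini-Hochberg adjustment, 255 of 8380 probe sets changed (3.04%), 147 higher and 108 lower in the mutant. Counted by the brightest probe set of each gene, 222 of 6855 genes changed, 128 higher and 94 lower. A separation of at least 2-fold between the nearest arrays of the groups was seen for 198 probe sets, 98 higher and 100 lower, against 27 when the arrays were split by replicate number and 13 when the numbers were crossed. For all 12 falls the mutant mean, and for 8 of the 12 rises the wild-type mean, lay below the signal of 39.5 used to leave out dim probe sets, so the size and order of these folds are uncertain; with 50 added to every signal they were 3.42 to 14.6 for the falls and 3.01 to 7.44 for the rises. The number of calls was 825 with the replicate number as a block, 95 without the mean-variance trend, 0 without the filter on dim probe sets (1782 at an unadjusted p under 0.05), and 153 and 140 without wild-type array 1 or 2 and 117 and 87 without mutant array 1 or 2.

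**Figure D1:**
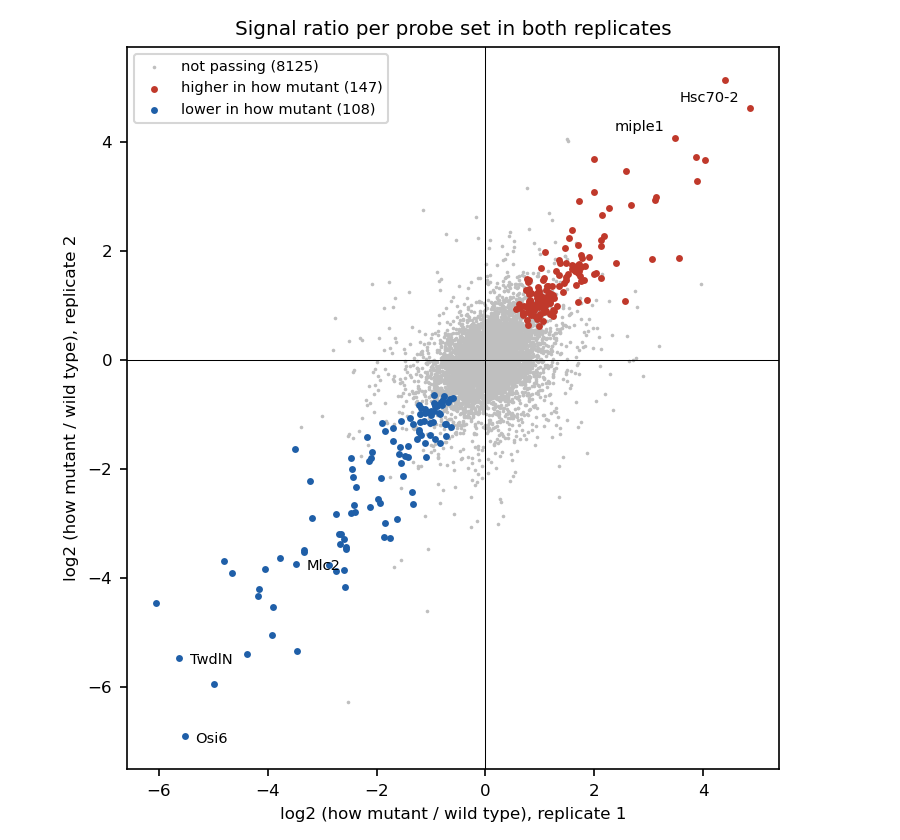
Log2 ratio of mutant to wild-type signal for each of the 8380 probe sets tested, in replicate 1 (x axis) and replicate 2 (y axis). The 147 probe sets higher in the mutant (red) and the 108 lower (blue) have the same sign in both replicates, with *Osi6* at -5.52 and -6.91 and *Hsc70-2* at 4.85 and 4.62. The calls were made on these same arrays, so the shared sign is not separate evidence.

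The second question was whether mRNAs linked to HOW in earlier work differed. *miple1*, a gene for a heparin-binding growth factor, rose from 23.5 ± 9.67 to 311 ± 39.4 (SD, n = 2), a log2 change of 3.78 ± 0.37 (SE). *Gli*, the gene for the septate junction protein Gliotactin, rose by 0.92 ± 0.19 (SE; limma adjusted p = 0.0497). The other 4 measured members did not pass: the sodium pump subunit gene *nrv2* at 0.85, *Nrx-IV* at -0.47, *dpp* at -0.22 and the splicing factor gene *crn* at 0.03. Thus 2 of 6 rose, and 2 rose when adjusted over the list alone. The choice of *miple1* for this list drew on published work on these samples. Neither the count nor the list tests that follow, which include *miple1*, are therefore independent evidence. Camera did not call the list (adjusted p = 0.23), while fry's mixed test, which asks whether genes change in either direction, gave an adjusted p of 0.0286, as 1 of 12 lists it called. *sr*, a tendon cell gene, and *bam* were too dim to be tested, with signals of 26.5 ± 28.5 and 15.8 ± 9.29 in wild type and 29.9 ± 32.4 and 26.7 ± 5.51 in the mutant (SD, n = 2). The call for *Gli* was lost under quantile normalization, median centring and a fit without the trend. It was also lost without either mutant array and without wild-type array 2. With the replicate block *nrv2* passed (limma adjusted p = 0.0384).

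The next question was which developmental gene groups moved, over 30 lists fixed before the data were examined. Genes of late embryonic differentiation were lower: 4 of 14 fell and 0 rose, and the list's median log2 change was -0.72. The list had been fixed as a sign of older embryos, so a difference in embryo age could also give these falls. The members that fell were the muscle gene *Mlc2* (-3.61), *obst-A*, whose product organises chitin in the cuticle (-2.79), *TwdlM* (-1.89) and the chitin deacetylase gene *verm* (-1.47). *Mlc2* went from 951 ± 45.3 to 77.9 ± 6.66 (SD, n = 2). A second probe set of *TwdlM* changed by -5.47. Adjusted over the list alone, 6 fell. This was the only one of the 28 lists with at least 5 tested members that limma's camera called with a preset correlation of 0.01 (adjusted p = 6.4e-05), and fry gave an adjusted p of 0.0149. With an estimated correlation no list was called, and for this list the adjusted p = 0.844 with an estimated correlation, on 2 residual degrees of freedom.

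In the list of myoblast fusion and muscle structure, 3 of 13 measured members fell, *Mlc1*, *Mlc2* and the troponin T gene *up* (-2.94; dim in the mutant, 7.68-fold or 3.20-fold with 50 added), and 0 rose, while the list's median was 0.33 and its mean -0.51. Adjusted over the list alone, 3 fell and 1 rose. Of 14 genes of the early mesoderm 13 did not pass, among them *twi* (-0.05) and *sna* (-0.16), and *lmd*, a regulator of fusion-competent myoblasts, rose by 1.02 ± 0.21 (SE). None of 10 genes of FGF receptor signalling passed (*htl*, the mesodermal receptor gene, -0.75; *btl*, its tracheal relative, -0.63). Among 11 gastrulation genes *fog*, which encodes a secreted signal for apical constriction, rose by 1.01. The calls for *lmd* and *fog* were lost under quantile normalization, median centring, a fit without the trend and a robust fit. That for *fog* was also lost without any 1 array, and that for *lmd* without either mutant array and without wild-type array 1. Those for *Mlc1* and *up* were lost without either wild-type array.

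Segmentation genes passed in no case: 0 of 10 gap and terminal genes (*hkb* -0.38, *kni* -0.27), 0 of 8 pair-rule genes (*hry* -0.57, *Ten-m* 0.38), 0 of 10 segment polarity genes (*nkd* 0.50, *mid* 0.43) and 0 of 4 Hox genes (*pb* 1.04, *Scr* 0.45). Likewise 0 of 20 neurogenic genes (*insc* 0.79, *numb* 0.72), 0 of 13 genes of dorsal ectoderm and amnioserosa (*ush* 0.82, *Dad* 0.91), 0 of 11 genes of trachea and salivary gland (*fkh* 0.42, *btl* -0.63) and 0 of 10 receptors and ligands of the Notch, Wnt and Hedgehog pathways (*H* 0.47, *boi* 0.24) passed. In the BMP pathway 1 of 14 genes rose, the receptor gene *put* (0.85). Among 11 genes of endoderm and blood cells the matrix gene *Ppn* fell (822 ± 24.2 to 412 ± 4.63, SD, n = 2), and among 21 genes of matrix and adhesion *SPARC*, which encodes a basement membrane protein, fell (-1.23) and *miple1* rose. Among 11 genes of ecdysone synthesis and response *ImpE2* fell (-1.10), and 4 fell when adjusted over the list alone. *ush* rose when adjusted over the list alone, both among dorsal ectoderm genes (1 of 13) and among endoderm and blood cell genes (1 of 11). With the replicate block *ush*, *insc* and *numb* passed too (limma adjusted p = 0.0119, 0.0396 and 0.00927). In simulated data only 26.9% of 2-fold changes were recovered, so smaller changes in these lists would mostly go undetected.

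Some germline genes rose and 1 fell, and 2 maternal transcripts rose. *tej*, which acts in the piRNA pathway, fell from 352 ± 9.28 to 67.3 ± 16.8 (SD, n = 2), a log2 change of -2.41 ± 0.25 (SE), whereas *spn-E* and *aub* of the same pathway rose by 1.79 ± 0.27 and 1.11 ± 0.20 (SE) and the pole cell gene *pgc* by 1.64 ± 0.34 (SE). *pgc* was dim in wild type, with a mean of 36.2, and its fold was 3.11, or 1.89 with 50 added. Of 12 pole cell and germline genes, 3 rose and 1 fell, and 3 rose and 2 fell when adjusted over the list alone. Of 19 maternal transcripts that are cleared early, 2 rose, *pgc* and the thioredoxin gene *dhd* (1.72 ± 0.18, SE), and the list's median was 0.33 (camera adjusted p = 0.173). Of 9 genes active during cellularisation of the blastoderm none passed (*halo* -0.84, *dia* -0.38), 8 lay below 0, and 1 fell when adjusted over the list alone. None of 5 eggshell and yolk genes passed (*Yp2* -1.17, *Vm26Aa* 0.42). The call for *pgc* was lost under quantile normalization, median centring, a robust fit and without any 1 array. Those for *spn-E* and *aub* were lost without either mutant array, and that for *aub* also without wild-type array 2. With the replicate block *halo* passed (limma adjusted p = 0.00543).

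Several genes of detoxification and stress rose. *GstE3* rose from 160 ± 23.99 to 1076 ± 68.8 (SD, n = 2), a log2 change of 2.76 ± 0.17 (SE). The cytochrome P450 gene *Cyp6d5* rose by 1.46, *GstE6* by 1.27, *Cyp4e2* by 1.19 and *GstD1* by 1.03, and *Cyp4p2* fell by 2.04 on the log2 scale. Of 20 members of that list 5 rose and 1 fell, and 8 rose and 2 fell when adjusted over the list alone. Its median was 0.28 and camera's adjusted p was 0.054, which became 0.0128 with the replicate block and 0.844 with an estimated correlation. Of 13 heat shock and stress genes 2 rose, the small heat shock gene *Hsp27* (1.68 ± 0.15, SE) and *GstD1*. *PGRP-SB1* was the 1 of 4 immune genes that rose.

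In the remaining lists few genes passed. Of 5 marker genes of laboratory stocks 1 rose, *ry*, the xanthine dehydrogenase gene (1.58 ± 0.18, SE), and *y*, mutated in the yw stock, had a log2 change of 0.11. Of 19 cell cycle genes *pim*, the securin gene, fell (-0.97). None of 26 ribosomal protein genes (*RpS27A* -0.37, *RpLP2* -0.30), 20 STAR and splicing regulators (*tra* -0.43, *tra2* -0.45) or 11 apoptosis genes (*skl* 0.54, *Dredd* 0.93) passed, though *Dredd* did with the replicate block (limma adjusted p = 0.0468). Of the ribosomal protein genes 23 of 26 lay below 0, with a median of -0.13 (camera adjusted p = 0.181). A fit without the trend also lost the calls for *CG2065*, *Ppn*, *spn-E*, *aub*, *TwdlM*, *verm*, *ImpE2*, *pim*, *GstD1*, *GstE6*, *put* and *SPARC*, and the call for *put* was lost under both scaling alternatives. Without either mutant array the calls for *Ppn*, *ImpE2*, *pim*, *GstD1* and *put* were lost, and without either wild-type array that for *SPARC*. Leaving out wild-type array 1 also lost those for *Ppn*, *ImpE2*, *pim* and *verm*, and leaving out wild-type array 2 those for *put* and *MtnA*. Leaving out mutant array 1 also lost those for *SPARC* and *verm*, and leaving out mutant array 2 those for *GstE6* and *axed*.

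**Figure D2:**
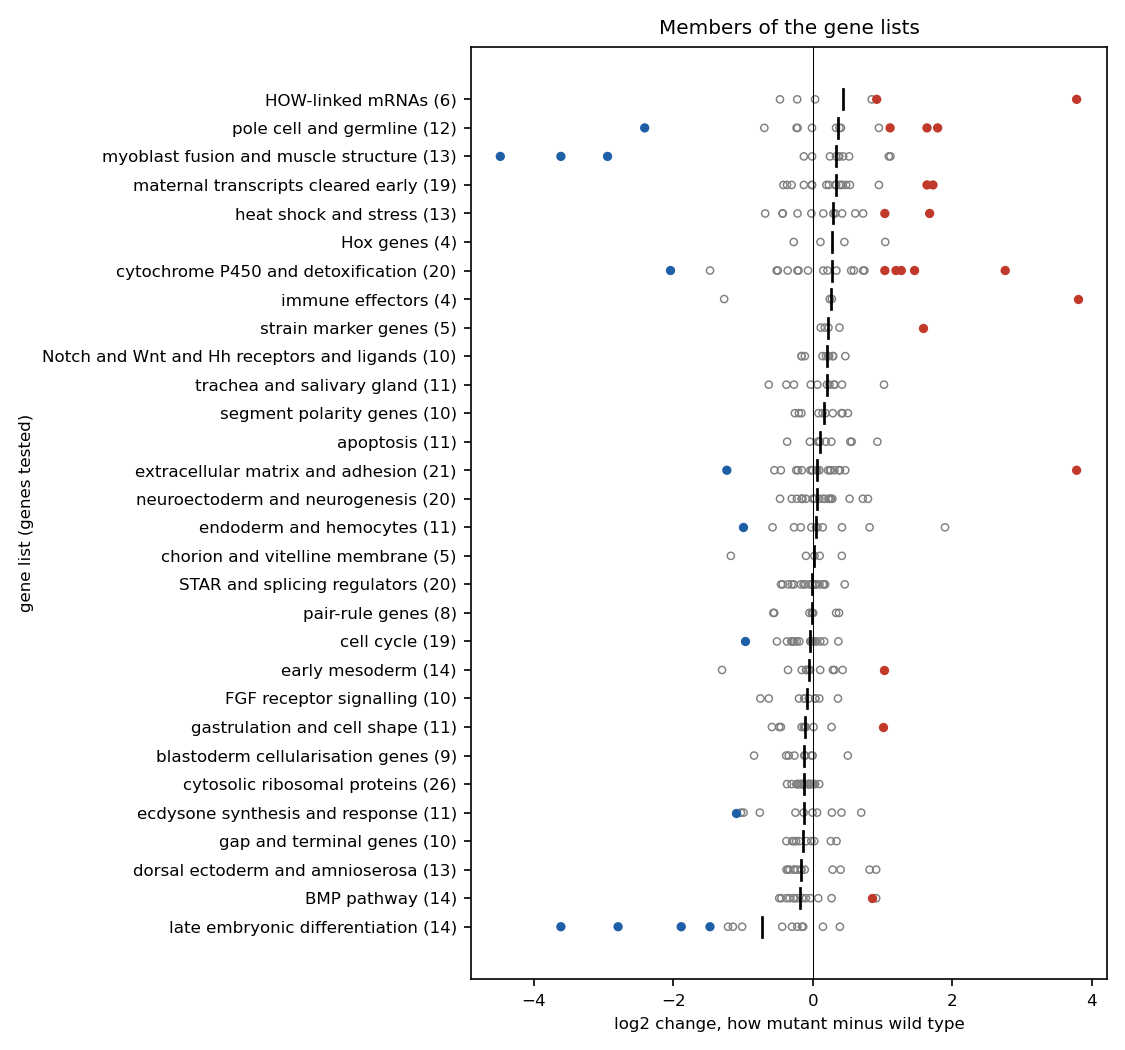
Log2 change, mutant minus wild type, of each tested gene (points) in the 30 lists, with the number tested in parentheses and the list's median as a black bar. Filled points passed limma's test (red higher, blue lower in the mutant) and open points did not; the late embryonic list has the lowest median, -0.72.

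**Figure D3:**
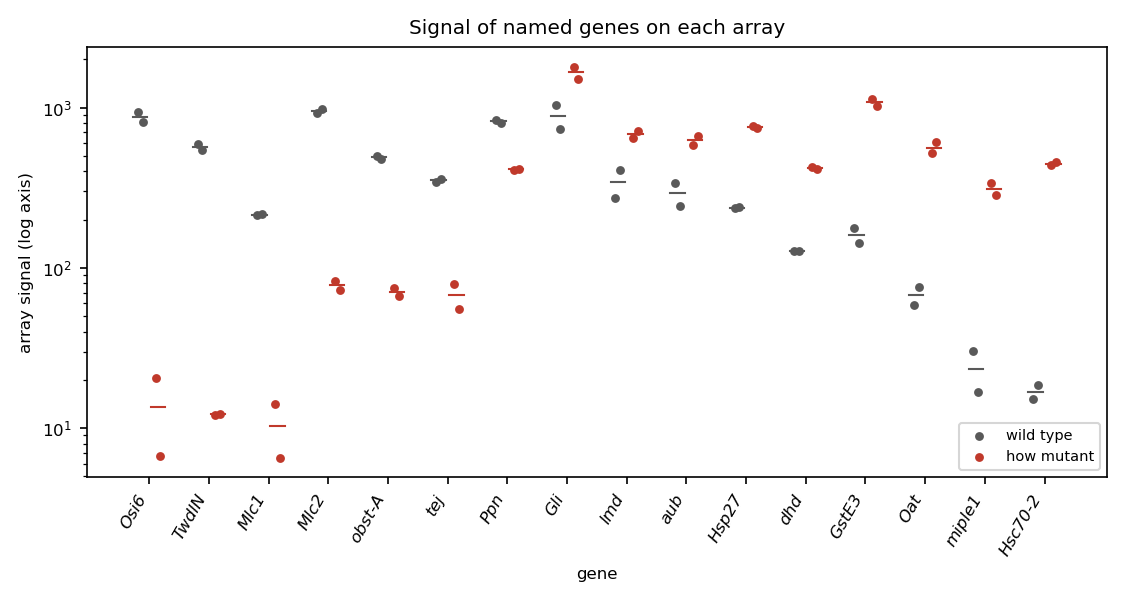
Signal on each of the 4 arrays (points, log axis) and group mean (bar) for 16 of the named genes, wild type in grey and *how* mutant in red. *Mlc2* had a mean of 951 in wild type and 77.9 in the mutant, and *GstE3* 160 and 1076.

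Chromosome arm 3R carries *how*, and the last question was whether changed genes lay there more often than other tested genes. Of 220 changed genes with a known arm, 63 lay on 3R, among them *Osi6*, *TwdlN* and *Mlc2*, which is 28.6% (exact 95% interval 22.8 to 35.1), against 24.5% of the 6838 genes tested (Fisher's exact test, two-sided, p = 0.151). Within 2 Mb of *how* 7 of 213 genes changed, 3.29% against 3.84% of the rest of the arm (Fisher's exact test, two-sided, p = 0.848). Split by direction, a comparison added after the data were seen, 22.2% of the genes that rose (p = 0.602) and 37.2% of those that fell (p = 0.00527) lay on 3R by the same exact test.

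The replicates were compared last. Across the probe sets tested, Pearson's r of log2 signal was 0.963 between the wild-type arrays, 0.966 between the mutant arrays and 0.926 to 0.938 between arrays of different groups. The log2 ratio of mutant to wild type correlated between replicate numbers with r = 0.545 and Spearman's rho = 0.410, and with r = 0.285 when dim probe sets were kept; these are correlations across genes, which are not independent replicates. The 12 probe sets for added poly-A control RNAs were a median 2.06-fold brighter on the arrays numbered 2 than on those numbered 1, with both arrays above both others for 10 of 12; the 4 at the 3′ end were 2.39-fold brighter (4 of 4). The 9 probe sets for hybridisation controls were 1.08-fold brighter (3 of 9). The 3′ to 5′ signal ratio of the actin control was 1.17 and 1.21 in wild type and 1.11 and 1.06 in the mutant. That of *eIF-4a* was 1.61 and 1.42 in wild type and 1.87 and 1.60 in the mutant. That of the dimmer *GAPDH* control was 1.17 and 1.47 in wild type and 0.973 and 1.95 in the mutant.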

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

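All settings here were chosen before the data were examined. For all 255 calls the arrays of the groups did not overlap. Leaving out an array, adding 50, the block, the filter or the variance settings could therefore not reverse their sign. Quantile normalization and median centring could have, and all 255 kept it there. No list that passed changed direction. Counts close to 255 came from quantile normalization (242), median centring (239), the 60th percentile filter (202), a robust fit (247), 50 added (306) and a 2-fold minimum (202). Others moved: 825 with the replicate block, 95 without the trend, 401 at an adjusted p under 0.1, and 0 with no filter, where limma's smallest adjusted p was 0.0891, 1782 probe sets had an unadjusted p under 0.05 and the prior degrees of freedom fell from 5.80 to 1.87. Leaving out an array gave 87 to 153, with fewer samples: 153 without wild-type array 1, 140 without wild-type array 2, 117 without mutant array 1 and 87 without mutant array 2, and the percent higher was 68.0, 66.4, 35.9 and 33.3; the lone array of a group is then assumed to vary like the other group. The count of separated probe sets, 198, was 80 at 3-fold, 578 with no filter, 80 with the 60th percentile filter, and 360 to 393 without an array, where fewer arrays need to part. The count of shifted lists, 1, was 2 with the replicate block, 2 with median centring, 3 with the 60th percentile filter, 0 with an estimated correlation and 1 to 2 without an array; detoxification was added in the first 3 and ecdysone genes in the third, ribosomal protein genes without wild-type array 1 and detoxification without mutant array 2, and the cause was not tested. The correlation of log2 ratios fell from 0.545 to 0.285 with no filter, which adds dim probe sets. The 3R share was 29.0% for separated genes (Fisher's exact p = 0.174); with no filter it has no value, since nothing was called. The level of *how* gave no value, and robust camera was not run. Of 48 named genes that passed, 48 passed with the block, 43 with quantile normalization, 33 without the trend and 0 with no filter. Without wild-type array 1 or 2, 14 and 13 of them lost the call, 9 of them both times, with 5 of the 12 largest falls (*CG13794*, *Mlc1*, *Ccp84Ag*, *CG9083*, *IM33*); without mutant array 1 or 2, 17 each did, 15 both times, with 4 of the 12 largest rises (*CG7650*, *PGRP-SB1*, *CG5973*, *CG2065*). *fog* and *pgc* lost it each time.

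The labels do not say that the replicate number marks a shared batch, so the block was not part of the main results. Deviations from the group means correlated with r = 0.183 between arrays of the same number, and 10 of 12 poly-A control probe sets were brighter on both arrays numbered 2, a hint from the data, not the design. All 255 calls were among the 825 made with the replicate block, which leaves 1 residual degree of freedom; 254 probe sets differed at least 2-fold the same way within each replicate number. Low signal limits the largest folds.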

Other observations

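The gene families in this part, and all tests in it with their bounds, were chosen after the results were seen, so their p-values describe these arrays and are not independent evidence. Cuticle families held some falls and 0 rises: 4 of 8 Osiris genes fell (*Osi6*, *Osi14*, *Osi7* at -3.37 and *Osi15* at -2.95; Fisher's exact adjusted p = 3.3e-05; median -1.91, or -0.39 over all 24 on the array), 3 of 10 Tweedle genes (*TwdlN*, *TwdlF* at -2.54 and *TwdlM*; 0.00105) and 3 of 31 other cuticle protein genes (*Ccp84Ag*, *Cpr65Ea* and *Cpr47Eg* at -2.27; 0.0182). Of 17 genes grouped as chitin deposition, 3 fell (*Muc55B* at -3.43, *obst-A* and *verm*) and *neo* rose by 0.94 (Fisher's exact adjusted p = 0.00443 for falls). The group was broader than its name: it also held chitinase genes (*Cht*), the mucin gene *Muc55B* and the apical matrix gene *neo*. *mmy* (-0.03), *kkv* (-1.01), *knk* (-0.22) and *serp* (-1.21) did not pass. Of 10 sarcomere genes 4 fell, *Mlc1*, *Mlc2*, *up* and *Mp20* at -2.57 (4.9e-05). The filter on mean signal leaves out some genes because they are dim in 1 group, such as *Osi20*, at 126 ± 0.87 in wild type and 8.57 ± 2.43 in the mutant (SD, n = 2). *Osi7* and *Muc55B* were dim in the mutant, and their folds of 10.4 and 10.8 became 3.48 and 5.15 with 50 added. With an estimated correlation, camera's adjusted p was 0.25 for Osiris genes and 0.214 for Tweedle and sarcomere genes, and it passed for no family.

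Genes of mitosis and chromosome segregation gave 6 falls and 0 rises among 50 (Fisher's exact adjusted p = 2.8e-04): *Map205* (-1.80), the separase gene *Sse* (-1.65), *Cap-H2* (-1.33), *Meics* (-1.25), *pim* (-0.97) and *Bub3* (-0.68). Folding enzymes of the endoplasmic reticulum gave 3 rises among 15, *ERp44* (0.87), *Fkbp14* (0.83) and *ERp60* (0.83; Fisher's exact adjusted p = 0.0368). Of 28 proteasome genes 2 rose, *Prosbeta6* (1.64) and *Rpt5* (0.94), and *Prosalpha6* fell (-0.80), with Fisher's exact adjusted p = 0.239 for rises and 0.482 for falls. The eye pigment gene *cn* rose by 2.22, beside *ry*, in a family of 12 with 2 rises (Fisher's exact adjusted p = 0.101). Of 8 blood cell matrix genes 2 fell, *Ppn* and *SPARC* (Fisher's exact adjusted p = 0.0123), but the family's median was 0.24 (camera adjusted p = 0.721). The filter left out *vkg* (mean signal 88.3 in wild type, 7.78 in the mutant) and *Tig* (44.0 and 6.41), which were dim in the mutant. It also left out *Hml* (9.79 and 15.3), *NimC1* (1.98 and 3.07) and *Glt* (5.53 and 2.69), dim in both groups. Over all 13 on the array the median was 0.20. Of 20 glutathione transferase genes 3 rose (Fisher's exact adjusted p = 0.0431), and of 25 cytochrome P450 genes 2 rose and 1 fell (0.236 for rises). Of 5 genes grouped as late nervous system and 17 genes of digestive enzymes 0 passed.

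The first pattern is the fall of late cuticle and muscle genes. Array scaling is argued against, since the median log2 change of all tested probe sets was 0.003. The late list's median after quantile normalization was -0.74 (95% bootstrap interval -1.50 to -0.19). The arrays had already been scaled to a common mean, so quantile normalization could shift values little and adds little to this. The bootstrap intervals here resample genes and not arrays. Mutant collections that were younger as a whole stay open: the cellularisation list had a median of -0.12 (-0.38 to -0.0015), but maternal transcripts had 0.33 (-0.01 to 0.43). A bound of 0.2 on the first list alone, tried first, would have excluded younger collections, and the maternal list was added after that value was seen. The mothers' germline genotype also differed between the groups, so maternal transcripts cannot separate embryo age from maternal genotype. A few older embryos among the wild type may also account for the fall of late genes. The late list had been fixed as a sign of older embryos. Its members that fell were bright in wild-type collections labelled 3 to 5 h, with means of 951 (*Mlc2*), 489 (*obst-A*), 1085 (*TwdlM*) and 314 (*verm*). When these genes normally come on was not examined here. The 5 genes grouped as late nervous system had a median of -0.027 (-0.83 to 0.15), and 5 genes are too few to decide. *jeb* alone (-0.83) sets the lower end, and whether it marks the nervous system at this age was not checked. The others were *repo* at -0.14, *Appl* at -0.03, *futsch* at 0.13 and *elav* at 0.15. Loss of HOW itself stays open and untested. Picking under a microscope is described above for the mutant embryos only, so its effect cannot be told apart from that of genotype.

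The second pattern is the share of 3R among genes that fell, 37.2%. Clusters of cuticle genes on 3R are a candidate explanation: 8 of 10 such genes that fell lie there, and outside these families the share was 32.1% (exact 95% interval 22.4 to 43.2) against 24.3% (Fisher's exact p = 0.0964), which leaves it undecided.

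The third pattern is the set of genes that rose, detoxification and heat shock genes among them. A share of 22.2% on 3R (15.3 to 30.5) argues against rises that lie mainly in genes on the arm of *how*. It cannot speak to differences on that arm that act on genes of other arms. The genetic background of the stocks may still contribute and was not tested, since each stock is in 1 group. Picking of the mutant embryos cannot be told apart from genotype here either. Loss of HOW stays open as well.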
